A study of Homo sapiens with 24 samples.

How the data were processed

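RNA from 24 libraries of the human leukemia cell lines KOPN-8 and NOMO-1 was sequenced, in 8 groups of 3 libraries. The deposited table holds 1 upper-quartile scaled signal per gene and library, made by the authors from RSEM gene estimates so that the upper quartile over all rows of a library is 1000. Per the labels, the authors used CASAVA, RSEM and Bowtie 0.12.9 with the human build hg19. The scaling was read from the values themselves, because the upper quartile lay between 999.8 and 1000 in every library. The values are therefore not counts, and no count model was fitted. In each library the smallest of the 3 most frequent values above 0 was read as 1 read, and 74.1% to 83.1% of the low values were whole multiples of it, within a tolerance of 0.1 of a read and over the first 20 multiples. That share is too low to recover counts, so the step served only to estimate depth. By this estimate 1 read corresponded to a value of 0.649 to 1.64, and the libraries held 21.2 to 50.1 M reads assigned to genes.

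The table had 22671 rows. In 28 of them the gene name had been turned into a calendar date, and these were left out, at 0.271% of a library or less. Of the 22643 names used, 16928 matched a current gene symbol, 2031 an older symbol only and 3684 neither. Names are printed as the table gives them, and names that match no symbol are counted but not printed. An annotation of the current human assembly (GENCODE, GRCh38) supplied symbols, transcript lengths and the order of neighbouring genes. The authors' own gene models on hg19 were not available, so no coordinates are given.

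Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, using moderated tests with a mean-variance trend and a mean for each group. The fit of each line used its 12 libraries and the genes with a value of at least 10 in at least 3 of them. P-values were adjusted over genes by the Benjamini-Hochberg method, all tests were two-sided, and a gene was called at an adjusted p below 0.05. The contrasts were treated minus control at day 10, resistant minus long-term control, and the difference between those responses (the interaction). Differences between the lines were tested in a fit of all 24 libraries. Fold changes are log2 values with their standard error (SE), and group values are means ± SD of the deposited values over 3 libraries. For single genes, an exact permutation test of 3 libraries against 3 cannot give a p below 0.1, so none is given. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the table and the figures.

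Before the data were examined, 28 gene lists, the tests, the alternatives and a rule for naming genes were fixed. The rule names the 10 genes with the largest rise and the 10 with the largest fall in each treated comparison. They had to be called, reach a mean of at least 100 in the higher group and show no overlap between the 3 treated and the 3 control libraries. For each interaction within a line it names the 5 most positive and 5 most negative called genes with a mean of at least 100 in at least 1 group. DOT1L, HOXA9, HOXA10, MEIS1, ABCB1, FLT3, BCL2, MYC, CDK6 and PBX3 are always reported, and members of a list with large changes may be named as its examples. No fold of a treated comparison is given where its control or treated group is listed at 0 in all 3 libraries. Differences between responses are given even where a group is listed at 0, and their size then depends on the pseudocount.

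The lists covered MLL fusion target genes, DOT1L and MLL complex members, ABC drug transporters, xenobiotic metabolism, myeloid and monocyte genes, B cell lineage genes, T and NK cell genes, erythroid and megakaryocyte genes, stromal and epithelial genes, and stem and progenitor genes. They also covered MHC class II presentation, MHC class I presentation, the interferon response, the NF-kB and inflammatory response, cell cycle and mitosis, CDK inhibitors and p53 targets, apoptosis regulators, and MYC targets and ribosome biogenesis. The remaining lists were RAS-MAPK output, receptor tyrosine kinases and cytokine receptors, RAS and PI3K pathway genes, WNT pathway targets, cholesterol biosynthesis, the unfolded protein and amino acid response, the heat shock response, other histone methylation enzymes, adhesion and migration, and housekeeping genes. Lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, with adjustment over the lists of a comparison. Each list is given as the members that rose, fell or did not pass, with counts adjusted over the list alone where those differ. Camera with an estimated correlation and fry were run as alternatives.

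The tests were tried on simulated data with the spread of the real genes, in which 200 genes of each fit were changed and 1 list of 25 genes was shifted by 2-fold. Of 2-fold changes, 89.6% were recovered in the KOPN-8 day 10 comparison, 83.6% in the KOPN-8 resistant comparison and 76.1% in the KOPN-8 interaction. The shares for NOMO-1 were 49.3%, 55.2% and 32.8%. For 4-fold changes they were 97.0%, 100% and 90.9% in KOPN-8, and 84.8%, 80.3% and 66.7% in NOMO-1. False calls made up 1.75% to 7.08% of the calls. The shifted list was found in each of the 6 comparisons, and 0 of 27 lists without a shift were called in any of them. Genes were simulated independently of each other, and most were left unchanged. The simulation therefore cannot show how often lists of correlated genes are called falsely. In the real fits of each line 50.9% to 83.4% of genes were called, which makes the adjusted threshold easier to pass. The shares recovered are therefore not the power of the real comparisons.

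The alternatives were pseudocounts of 0.1 and 10, no filter and a filter at 50, rescaling by the median of ratios, quantile normalization, limma without the trend or with robust hyperparameters, a fit of only the 6 libraries compared, a minimum change of 1.5-fold, and leaving out each library in turn. After the data were seen, 4 were added: genes with a mean of at least 300, scaling to the total without 4 structural RNA rows, scaling to the median of 12 housekeeping genes, and cyclic loess. The labels number the replicates, but the columns of the table carry a group and no replicate number, so columns were not tied to numbered samples. Libraries are named here by column order within their group, which carries no meaning.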

Results

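KOPN-8 is a B cell precursor acute lymphoblastic leukemia line in which MLL is fused to MLLT1, and NOMO-1 is an acute monocytic leukemia line in which MLL is fused to MLLT3. Fusion proteins of this kind recruit DOT1L, the methyltransferase of lysine 79 of histone H3, to genes such as HOXA9 and MEIS1. Both lines had been exposed to 4.5 µM pinometostat, a DOT1L inhibitor. Cells of each line that had become resistant, after 28 days for KOPN-8 and 53 days for NOMO-1, were compared with cells kept in the DMSO vehicle, here called the long-term control. The labels give no day for the NOMO-1 long-term control, which was taken from its name to be the control of the resistant cells. Cells that had never met the drug were treated for 10 days, with their own day 10 control in DMSO. The 8 groups let 3 questions be asked of each line: what 10 days of treatment changed, what differed in resistant cells, and whether those responses differed. The 3 replicates of a group share a cell pellet name in the labels, so the p-values measure the spread between these libraries only, which may be technical. In addition, 2 KOPN-8 day 10 treated samples carry the same L number, so these may not be 3 distinct samples. The pellets of the NOMO-1 resistant cells and of their control carry different days of September, 17 and 9, so treatment and collection cannot be told apart there.

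KOPN-8 libraries held an estimated 38.5 to 50.1 M reads and NOMO-1 libraries 21.2 to 40.5 M. In NOMO-1, the treated libraries differed from their controls in composition (library composition figure). The 7SL RNA of the signal recognition particle, which is not polyadenylated, took 28.1% ± 11% of the day 10 treated libraries and 12% ± 4.47% of the resistant ones. In the day 10 and long-term controls it took 4.30% ± 0.221% and 6.33% ± 1.29% (means ± SD, n = 3). Ribosomal protein genes, abundant in growing cells, made up 0.587% and 2.03% of the day 10 treated and resistant libraries and 5.32% and 5.30% of their controls. Olfactory receptor genes, which blood cells are not known to need, reached 82.6 ± 14.9 and 82.8 ± 5.61 ppm of the signal in the day 10 treated and resistant cells, against 18.7 ± 5.50 and 39.9 ± 5.61. In KOPN-8 the long-term control differed in composition from the other groups, with 6.84% of 7SL RNA against 4.01% to 4.30%, a housekeeping median of 31998 against 19835 to 23072, and 12 ppm of olfactory receptor signal against 6.36 to 9.23. The housekeeping median is over the values of 12 genes within a library. Gene by gene, 8 of them were called lower and 3 higher in the long-term control than in the day 10 control (median change -0.25). Ribosomal protein genes made up 7.66% to 9.78% of single KOPN-8 libraries.

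**Figure D1:**
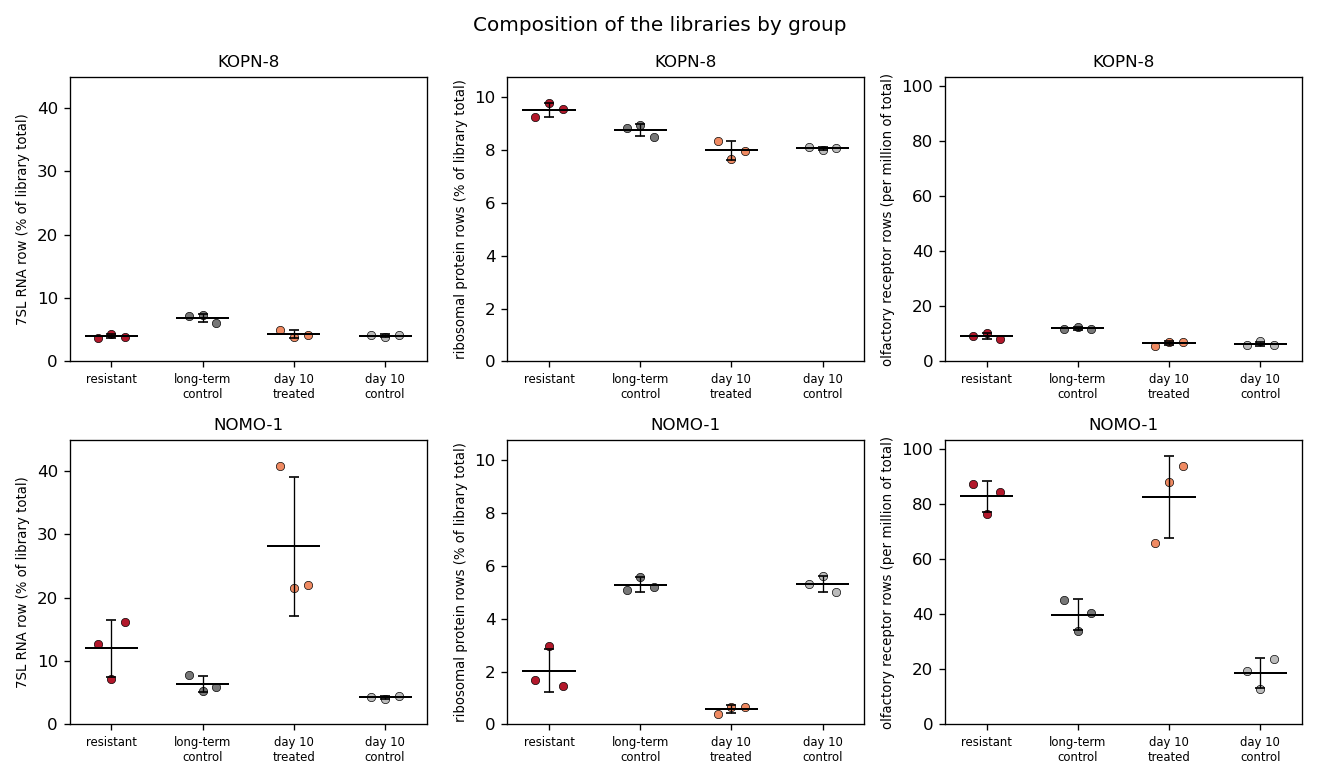
Share of 7SL RNA, share of ribosomal protein genes and olfactory receptor signal (in ppm of the total) in the 24 libraries. Points are libraries, lines group means and bars SD (n = 3).

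In KOPN-8, most of the listed genes that MLL fusion proteins are known to bind were lower after 10 days of pinometostat, and CYBB and CD180 were among the genes that rose most. HOXA9, a homeobox gene that sustains leukemic growth, went from 3322 ± 173 to 903 ± 27.7 (log2 fold change -1.88, SE 0.041), and its partner MEIS1 from 7066 ± 160 to 1688 ± 27.5 (-2.06, SE 0.030). HOXA11 fell most among the homeobox genes named for this comparison, from 1536 ± 76.9 to 26.9 ± 1.77 (-5.78, SE 0.060). CYBB, the catalytic subunit of the phagocyte oxidase, rose from 4.11 ± 1.17 to 1395 ± 50.7 (8.12, SE 0.268). CD180, a receptor on B cells, rose from 105 ± 10.4 to 2999 ± 27.8 (4.82, SE 0.074). All values are for 3 libraries a group (named genes figure).

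Of the 29 measured MLL fusion target genes, 3 rose, 26 fell and 0 did not pass (median -1.50, adjusted p = 3.05e-15). HOXA11 (-5.78), PROM1 (-3.91) and BMI1 (-3.50) fell most. Among other members FLT3, a cytokine receptor, was at -1.60 and CDK6, a cell cycle kinase, at -1.50. The anti-apoptotic gene BCL2 fell by 2.12, from 7022 ± 25.9 to 1619 ± 21.8. HOXA10 (-2.40), PBX3 (-0.89), MYC (-0.50) and DOT1L itself (-0.59) were also lower. Stem and progenitor genes fell (2 rose, 9 fell, 0 not passed, median -1.15, adjusted p = 0.000962), led by the transcription factor ERG (-6.82), SPINK2 (-3.92) and IGF2BP2 (-2.27). Cholesterol biosynthesis fell (1 rose, 22 fell, 0 not passed, median -0.84, adjusted p = 4.14e-13), with DHCR7 at -1.59, INSIG1 at -1.42 and FDPS at -1.21. These 3 lists stayed called with an estimated correlation.

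The calls of 9 further lists were lost with an estimated correlation. B cell lineage genes rose (17 rose, 8 fell, 4 not passed, adjusted p = 0.00386, adjusted p = 0.105 with an estimated correlation; 18 rose when adjusted over the list alone). MS4A1, which encodes CD20, rose by 3.76 and the B cell receptor component CD79B by 1.59, while the early B cell genes RAG1 (-1.91) and IGLL1 (-1.95) fell. MHC class II genes rose (11 rose, 2 fell, 1 not passed, adjusted p = 0.00700; adjusted p = 0.186 with an estimated correlation), with HLA-DOB at 0.53. MYC targets and ribosome biogenesis rose (17 rose, 3 fell, 6 not passed, adjusted p = 0.00212; adjusted p = 0.175 with an estimated correlation), ODC1 by 0.78, and 4 fell when adjusted over the list alone. MHC class I genes fell (0 rose, 10 fell, 2 not passed, median -0.40, adjusted p = 0.000130; adjusted p = 0.102 with an estimated correlation), with PSMB8 at -0.73. Cell cycle and mitosis fell slightly (2 rose, 23 fell, 7 not passed, median -0.19, adjusted p = 0.000152; adjusted p = 0.264 with an estimated correlation), with PLK1 at -0.62, while CCNE1 rose by 0.64.

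The NF-kB and inflammatory list fell (2 rose, 11 fell, 2 not passed, median -0.61, adjusted p = 0.000779; adjusted p = 0.0947 with an estimated correlation), with TNFAIP3 at -1.79 and IL1B at -1.45. RAS-MAPK output fell (4 rose, 15 fell, 3 not passed, median -0.45, adjusted p = 0.00212; adjusted p = 0.154 with an estimated correlation), with the phosphatase DUSP4 at -1.88, while JUN rose by 1.75. WNT targets fell (1 rose, 9 fell, 4 not passed, median -0.49, adjusted p = 0.010; adjusted p = 0.0947 with an estimated correlation), with NOTUM at -2.90. Receptor tyrosine kinases and cytokine receptors fell (2 rose, 8 fell, 7 not passed, median -0.19, adjusted p = 0.0383; adjusted p = 0.365 with an estimated correlation), with FGFR1 at -2.41.

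The other largest rises were of KLHL14 (6.39), RUNDC2B (5.40), the B cell Fc receptor-like genes FCRL4 (5.18) and FCRL5 (4.36), the kinase FGR (5.15), the lipid-presenting CD1C (4.72), MS4A6A (4.69) and PLCH2 (4.21). The other largest falls were of TGFBI (-6.62), the cytokine signaling suppressor SOCS2 (-6.16), HOXA11-AS1 (-6.08), NPTX1 (-5.73), C10orf114 (-5.40), GNPDA1 (-5.08) and PPFIA4 (-4.04), with 1 gene that has no official symbol. In all, 8644 of 15080 genes were called, 4492 higher and 4152 lower, and 602 and 812 of them changed at least 2-fold. The treated and control values did not overlap in 62.8% of genes, where chance gives 10%. The call of the receptor list was lost without treated library 1 (adjusted p = 0.068), without a filter and among genes with a mean of at least 300, which also ended the calls of the stem cell and WNT lists.

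**Figure D2:**
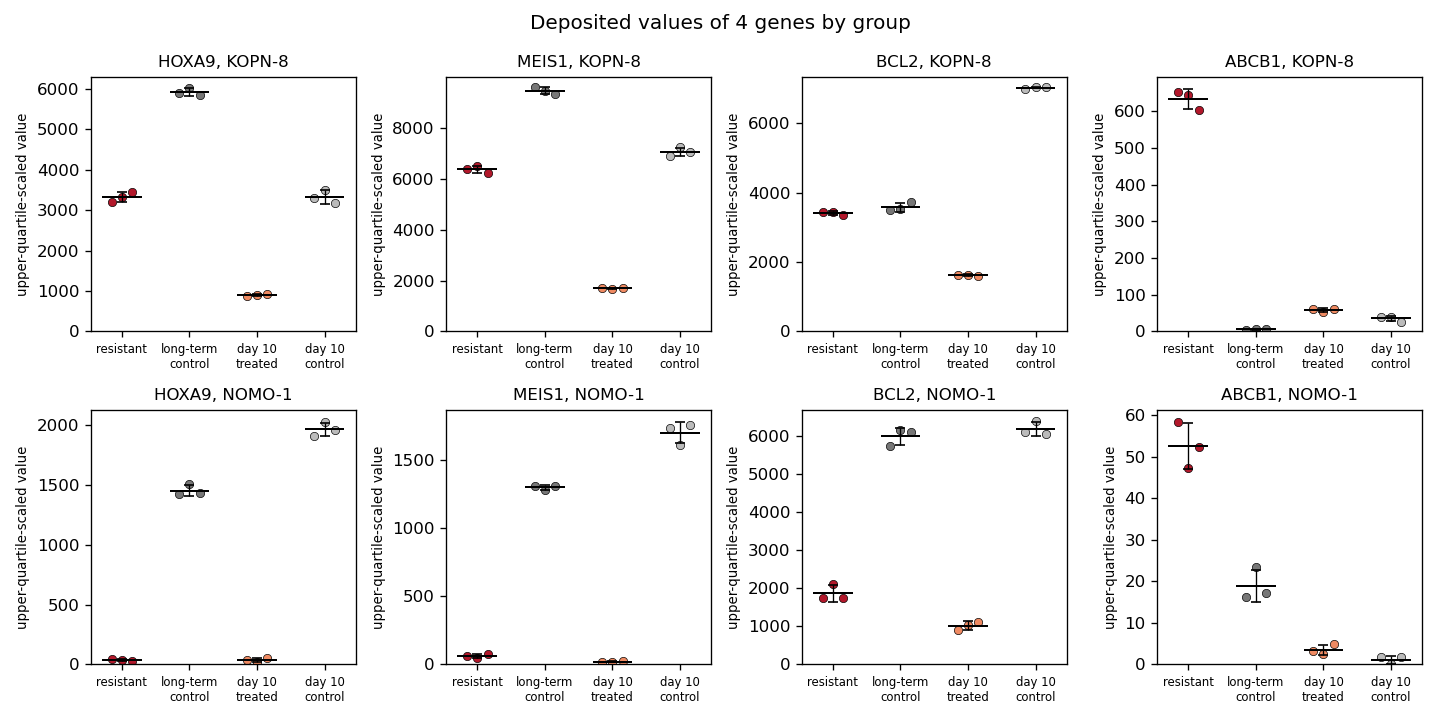
HOXA9, MEIS1, BCL2 and ABCB1 in the 4 groups of each line. Points are libraries, lines group means and bars SD (n = 3) of the deposited values. The NOMO-1 differences in ABCB1 change direction under cyclic loess, and at day 10 also under quantile normalization.

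In resistant KOPN-8 cells the drug efflux pump ABCB1 was among the genes that differed most from the long-term control. It stood at 634 ± 26.4 against 5.72 ± 1.55 (6.59, SE 0.187, adjusted p = 3.23e-14). The day 10 treated and control cells held 58.5 ± 4.97 and 35.5 ± 7.66 (0.72, SE 0.187, adjusted p = 0.00332). Cell cycle genes were higher and MLL fusion target genes lower, though both calls were lost with an estimated correlation (adjusted p = 0.151 and 0.417). In both lists the long-term control lay further from the day 10 control than resistant cells did, as given below. HOXA9 stood at 3317 ± 121 against 5923 ± 97.0 (-0.84, SE 0.041), with 3322 ± 173 in the day 10 control, and MEIS1 at 6371 ± 151 against 9466 ± 127 (-0.57, SE 0.030). BCL2 was not called (3414 ± 51.3 against 3575 ± 128, -0.07, adjusted p = 0.075), and neither was DOT1L (0.03, adjusted p = 0.643). BCL2 became called under quantile normalization (-0.13), total scaling (-0.12), cyclic loess (-0.15) and housekeeping scaling (-0.27), the last of which also called DOT1L (-0.17).

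Cell cycle and mitosis genes rose (31 rose, 0 fell, 1 not passed, median 0.76, adjusted p = 7.06e-17; adjusted p = 0.151 with an estimated correlation). CCNE1 rose by 2.29, E2F2 by 1.44 and CDC45 by 1.39, and PLK1 was at -0.10. The long-term control was the group apart: relative to the day 10 control the list median was -0.88 there, with 31 of 32 genes lower, -0.14 in resistant cells and -0.19 in day 10 treated cells. This second reference was chosen after the data were seen, and a shift between the experiments cannot be told apart from a change in the long-term control. That group also held the most 7SL RNA and the highest median housekeeping value in KOPN-8. Gene by gene, however, 8 of 12 housekeeping genes were called lower there than in the day 10 control, and 3 higher. MLL fusion target genes fell (6 rose, 20 fell, 3 not passed, median -0.35, adjusted p = 0.00613; adjusted p = 0.417 with an estimated correlation). PROM1 was at -2.94, RUNX1 at -1.46, FLT3 at -1.24, PBX3 at -1.19 and HOXA10 at -0.56, while LAMP5 rose by 4.72. Relative to the day 10 control the list median was 0.38 in the long-term control, -0.15 in resistant cells and -1.50 in day 10 treated cells. MYC (-0.40) and CDK6 (-0.24) were lower.

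Cholesterol biosynthesis rose, opposite to its day 10 fall (17 rose, 5 fell, 1 not passed, median 0.18, adjusted p = 0.0237; adjusted p = 0.474 with an estimated correlation), PMVK by 0.83, and 6 fell when adjusted over the list alone. RAS and PI3K pathway genes rose (14 rose, 5 fell, 9 not passed, median 0.08, adjusted p = 0.0424; adjusted p = 0.501 with an estimated correlation), the kinase MTOR by 1.40. The direction of both lists turned under housekeeping scaling, to medians of -0.02 and -0.12. RAS-MAPK output fell (6 rose, 16 fell, 0 not passed, median -0.53, adjusted p = 0.0237; adjusted p = 0.474 with an estimated correlation), with FOSB at -2.84, FOS at -1.84 and SPRY2 at 1.23. Receptor tyrosine kinases and cytokine receptors fell (2 rose, 10 fell, 5 not passed, median -0.47, adjusted p = 0.0424; adjusted p = 0.474 with an estimated correlation), with PDGFRB at -2.51. The heat shock list fell (2 rose, 7 fell, 3 not passed, median -0.34, adjusted p = 0.0424; adjusted p = 0.474 with an estimated correlation), with the chaperones HSPA1A at -5.06 and HSPA1B at -2.49. Relative to the day 10 control, RAS-MAPK output had a median of 0.42 in the long-term control and 0.12 in resistant cells. For RAS and PI3K genes these were -0.14 and 0.002, so in both lists resistant cells were nearer the day 10 control. They were 0.31 and -0.31 for receptors, 0.003 and 0.22 for cholesterol, and -0.19 and -0.51 for heat shock.

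The largest positive difference was of MS4A1, at 12525 ± 179 against 18.7 ± 2.47 (9.32, SE 0.062). RHOBTB1, PRICKLE2 and FAM81A were listed at 0 in the 3 control libraries and had means of 420, 239 and 187 in resistant cells. TLL1 (8.25), ZNF175 (7.04), the hedgehog pathway factor GLI3 (6.95), WDR11 (6.77), the protein kinase A inhibitor PKIA (6.75) and MINPP1 (6.70) followed. The largest negative differences were of ERG (-7.96), the creatine transporter SLC6A8 (-7.84), the serotonin receptor HTR1F (-7.77), OSR2 (-6.48), FAM127B (-6.41), DNAJC15 (-6.16), TRO (-5.91), TNS1 (-5.90), SPG20 (-5.60) and MAGED4B (-5.15). At many of these genes the long-term control was a group apart, at least 4-fold from each of the other 3 groups: MS4A1, RHOBTB1, FAM81A, ZNF175, GLI3, WDR11, PKIA, MINPP1, SLC6A8, OSR2, DNAJC15, TNS1 and SPG20. Relative to the day 10 control MS4A1 was at -6.34 there and at 2.98 in resistant cells. In all, 9884 genes were called, 4536 higher and 5348 lower, with 866 and 858 at least 2-fold, and 69.0% showed no overlap (10% by chance). The calls of the heat shock, receptor and RAS and PI3K lists each ended without long-term control library 1 (adjusted p = 0.058 for all 3), and heat shock also without library 2 (0.071) or 3 (0.080) of that group or day 10 treated library 1 or 2 (both 0.056), RAS and PI3K without library 2 (0.069) and receptors without library 3 (0.055). All 3 calls also ended among genes with a mean of at least 300 and in a fit of the 6 libraries compared. Heat shock further ended with a pseudocount of 0.1 (0.0518), the median of ratios (0.0510), no trend (0.0630) and a filter at 50 (0.0727), as did RAS and PI3K with that filter. RAS and PI3K and receptors ended under cyclic loess (0.310 and 0.0596), total scaling (0.0886 and 0.0506) and housekeeping scaling (0.273 and 0.0687), and RAS and PI3K also under quantile normalization (0.176). RAS-MAPK output ended under housekeeping scaling (0.0723). The NF-kB list, not called here (adjusted p = 0.0698), was called without any 1 of the resistant libraries (0.00740 to 0.0167), and the cholesterol call ended under quantile normalization (0.176), cyclic loess (0.289), housekeeping scaling (0.226) and a mean of at least 300 (0.0746). Higher genes went from 45.9% to 24.9% of the calls under housekeeping scaling, which shifted the median of all genes from -0.07 to -0.27, and to 38.9% under total scaling, but were the larger part under the median of ratios (5100 higher, 4598 lower). They were also the larger part when tested against a minimum change of 1.5-fold (1095 higher, 939 lower). The median change ran from -0.25 in the scarcest quintile of genes to 0.08 in the most abundant.

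**Figure D3:**
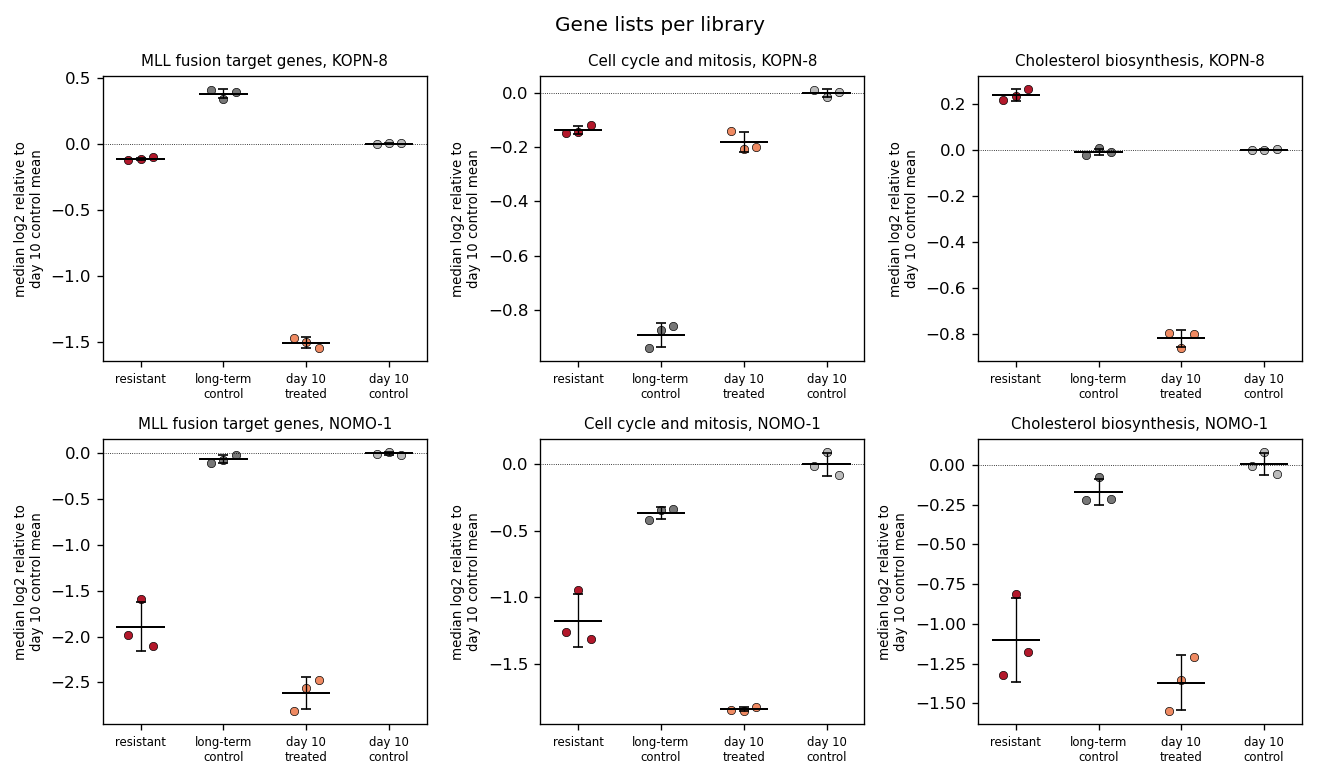
Median log2 value of the MLL fusion target, cell cycle and cholesterol lists in each library, relative to the mean of the day 10 control of the line. Points are libraries, lines group means and bars SD (n = 3). The NOMO-1 falls of the cell cycle and cholesterol lists turn under housekeeping scaling, as does the cholesterol rise of resistant KOPN-8.

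The KOPN-8 interaction asked whether resistant cells differed from their control in the way that day 10 cells did. MLL fusion target genes, cell cycle genes and cholesterol biosynthesis were more positive in the resistant response, and so was ABCB1. Relative to the day 10 control, the cell cycle median was -0.14 in resistant cells and -0.19 in day 10 treated cells, against -0.88 in the long-term control. The controls come from different experiments, so a shift between these cannot be told apart from a change in the long-term control. The difference was 5.86 (SE 0.264) for ABCB1, 2.05 (SE 0.044) for BCL2, 1.84 for HOXA10, 1.49 for MEIS1, 1.26 for CDK6, 1.04 for HOXA9, 0.62 for DOT1L and 0.36 for FLT3. ABCB1 was lower in the long-term control (5.72) than in the day 10 control (35.5), so part of its difference lies between the controls. BCL2 in resistant cells (3414) and in the long-term control (3575) was below the day 10 control (7022), so its difference is no return to that level. The difference was -0.30 for PBX3 and 0.10 for MYC, which was not called (adjusted p = 0.0842) but was without resistant library 2 (0.13, adjusted p = 0.0125). MYC was also called under the median of ratios (0.15, adjusted p = 0.0157).

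Cell cycle and mitosis (32 higher, 0 lower, 0 not passed, median 1.04, adjusted p = 2.10e-19), cholesterol biosynthesis (21 higher, 0 lower, 2 not passed, median 0.93, adjusted p = 5.92e-13) and MLL fusion targets (23 higher, 4 lower, 2 not passed, median 1.07, adjusted p = 7.03e-10) stayed called with an estimated correlation. The heat shock list was lower (1 higher, 8 lower, 3 not passed, median -0.57, adjusted p = 0.00287; adjusted p = 0.329 with an estimated correlation), with HSPA1A at -5.06, HSPA1B at -2.25 and HSPH1 at -1.19. MHC class II genes were lower (1 higher, 11 lower, 2 not passed, median -0.25, adjusted p = 0.00960; adjusted p = 0.329 with an estimated correlation), 12 of them when adjusted over the list alone. In all, 8841 genes differed, 4232 higher and 4609 lower, a balance that turned under the median of ratios (4668 and 3978) and cyclic loess (4367 and 4322). TLL1 (7.37), CARKD (6.99) and WDR11 (6.64) were among the most positive, SLC6A8 (-8.33), OSR2 (-6.45), DNAJC15 (-6.30), TRO (-6.16) and FAM127B (-6.08) the most negative.

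Of the genes raised at day 10 in KOPN-8, 1938 were also higher in resistant cells (1351 if the calls were independent) and 1262 were lower. Of those lowered, 2015 were also lower (1472 if independent) and 1152 were higher. The median resistant change was 0.07 over the raised genes, which turned to -0.13 under housekeeping scaling, and -0.15 over the lowered ones (-0.36 there). For changes of at least 2-fold in both, 270 genes were shared upward and 301 downward, against 34.6 and 46.2 if independent.

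In NOMO-1, cells treated with pinometostat for 10 days had lower levels of most MLL fusion target, cell cycle, amino acid response and heat shock genes. With an estimated correlation none of the list calls of this comparison held (lowest adjusted p = 0.231), and the cell cycle and amino acid response medians turned to 0.19 and 0.12 under housekeeping scaling. HOXA9 went from 1967 ± 56.6 to 35.2 ± 17.4 (-5.90, SE 0.303) and MEIS1 from 1704 ± 77.1 to 19.9 ± 4.27 (-6.37, SE 0.182). The neutrophil defensin DEFA1 rose from 4.24 ± 1.72 to 20684 ± 6276 (11.95, SE 0.603) and lactoferrin, LTF, from 0.811 ± 0.056 to 2317 ± 130 (10.32, SE 0.413), while the granule genes CTSG (-4.98), PRTN3 (-2.79) and MPO (-2.17) fell. The protease gene GZMA fell from 2626 ± 402 to 0.403 ± 0.699 (-10.97, SE 0.291). These are the libraries with 28.1% of 7SL RNA. Scarce genes were higher and abundant ones lower in them: the median change was 1.91 in the scarcest quintile of genes and -0.19 in the most abundant (abundance figure).

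MLL fusion target genes fell (3 rose, 23 fell, 3 not passed, median -2.61, adjusted p = 2.73e-07; adjusted p = 0.231 with an estimated correlation). HOXA7 went from 414 ± 17.3 to 0 in all 3 libraries, and HOXA5 (-7.11), BMI1 (-6.48), HOXA10 (-5.86), FLT3 (-5.38), CDK6 (-4.66), PBX3 (-2.98) and BCL2 (-2.61) fell, while EYA1 rose by 2.25, CPEB2 by 1.77 and RUNX1 by 0.81. MYC fell by 1.48, which turned to 0.51 under housekeeping scaling (adjusted p = 0.00987), and DOT1L rose by 1.19. ABCB1 was barely detected, at 3.52 ± 1.23 against 1.13 ± 0.979 (1.19, adjusted p = 0.0168), and its direction turned under quantile normalization (-0.78) and cyclic loess (-0.98). Without treated library 3 or control library 2 its call was lost (adjusted p = 0.061 and 0.079), as it was with a pseudocount of 10 (0.28, adjusted p = 0.116).

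Cell cycle and mitosis fell (2 rose, 30 fell, 0 not passed, median -1.80, adjusted p = 5.81e-10; adjusted p = 0.231 with an estimated correlation), with the replication genes PCNA at -3.40 and TYMS at -3.37 and the cyclins CCNA2 at -3.19 and CCNB1 at -2.86. E2F2 (0.63) and E2F1 (0.48) rose. The unfolded protein and amino acid response fell (1 rose, 20 fell, 3 not passed, median -1.86, adjusted p = 6.97e-08; adjusted p = 0.231 with an estimated correlation). Its serine synthesis genes PHGDH (-7.38) and PSAT1 (-5.97), CHAC1 (-4.60) and asparagine synthetase, ASNS (-4.16), fell most. MYC targets and ribosome biogenesis fell (1 rose, 21 fell, 4 not passed, median -1.51, adjusted p = 1.85e-07; adjusted p = 0.231 with an estimated correlation), with NME1 at -3.51 and NPM1 at -3.22. Cholesterol biosynthesis fell (1 rose, 20 fell, 2 not passed, median -1.43, adjusted p = 2.92e-07; adjusted p = 0.231 with an estimated correlation), with DHCR7 at -3.59 and CYP51A1 at -2.80.

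Heat shock genes fell (0 rose, 10 fell, 2 not passed, median -2.08, adjusted p = 5.65e-05; adjusted p = 0.332 with an estimated correlation), with HSPE1 at -3.39. MHC class I genes (2 rose, 10 fell, 0 not passed, median -0.90, adjusted p = 0.00864; adjusted p = 0.473 with an estimated correlation) and MHC class II genes (3 rose, 9 fell, 2 not passed, median -1.10, adjusted p = 0.0283; adjusted p = 0.473 with an estimated correlation) fell. B2M was at -2.92 and HLA-DRA at -4.19, while the regulators NLRC5 and CIITA rose by 2.17 and 2.40. All 12 housekeeping genes fell too (median -1.92, adjusted p = 4.32e-05; adjusted p = 0.423 with an estimated correlation), with PPIA at -3.36 and GAPDH at -2.63. Scaled to these genes, the medians of the MHC class II (0.89), MHC class I (1.08), cell cycle (0.19), MYC target (0.48), cholesterol (0.56), amino acid response (0.12) and housekeeping (0.07) lists turned positive, and those of MLL targets and heat shock stayed negative. The MHC class I call ended under quantile normalization (adjusted p = 0.158), cyclic loess (0.184), housekeeping scaling (0.562) and a mean of at least 300 (0.0870), and the class II call with a filter at 50 (0.0557) and a mean of at least 300 (0.158).

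The other largest rises were of IGFN1 (10.44), CNTNAP3 (9.83), LINC00273 and FAM196B, with the last 2 listed at 0 in the control libraries and at 1438 ± 1461 and 955 ± 264 in treated ones, so that the libraries disagree widely on LINC00273. A further 4 had no official symbol. The other largest falls were of the chemokine gene CXCL10 (-9.35), FAM25B (-8.79), VAT1L (-8.41), SOCS2 (-8.15), CHRDL1 (-7.98) and the collagen gene COL1A2 (-7.98), and of 2 genes without an official symbol. In all, 15558 of 18653 genes were called, 9400 higher and 6158 lower, with 7393 and 4047 at least 2-fold, and 84.1% showed no overlap (10% by chance). The median of all genes, 0.46, was 0.13 with the median of ratios, 0.01 with quantile normalization, -0.04 with cyclic loess, 0.59 with total scaling and 2.39 with housekeeping scaling. Higher genes, 60.4% of the calls, were 49.1% under cyclic loess, 48.8% among genes with a mean of at least 300 and 93.3% under housekeeping scaling.

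**Figure D4:**
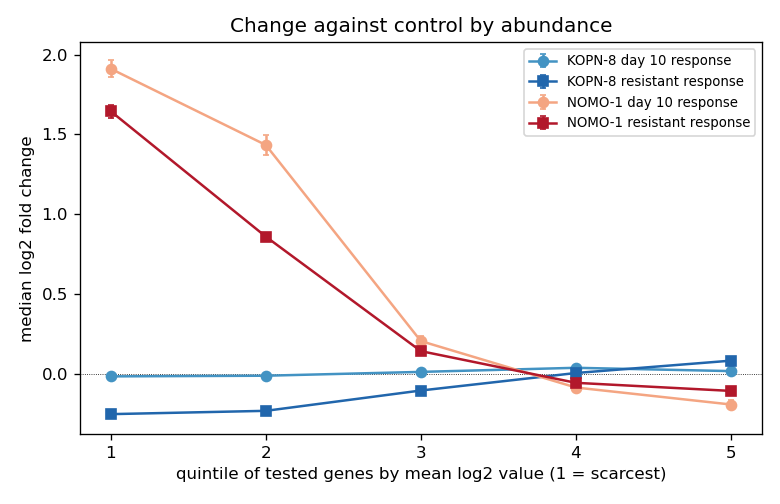
Median log2 fold change in quintiles of genes by mean abundance, for the 4 treated comparisons. Error bars are the bootstrap SD of the median.

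In resistant NOMO-1 cells MLL fusion target genes were lower than in the long-term control, as in day 10 cells, and most ABC drug transporters were higher. Both list calls were lost with an estimated correlation (adjusted p = 0.203 and 0.439), and that of the transporters under housekeeping scaling (adjusted p = 0.133). Lists of other cell types had raised medians in the same libraries without a call: T and NK cell genes 1.59, erythroid and megakaryocyte genes 0.88 and B cell lineage genes 0.71, against 1.03 for the transporters. HOXA9 stood at 38.9 ± 8.52 against 1455 ± 44.7 (-5.21, SE 0.303) and MEIS1 at 62.1 ± 14.1 against 1303 ± 17.4 (-4.39, SE 0.182). BCL2 stood at 1863 ± 218 against 5987 ± 223 (-1.69, SE 0.101) and FLT3 at 656 ± 105 against 3288 ± 89.4 (-2.33, SE 0.238). ABCB1 stood at 52.6 ± 5.56 against 18.9 ± 3.95 (1.44, SE 0.407, adjusted p = 0.00712), a difference that turned under cyclic loess (-0.64) and was not called with a pseudocount of 0.1 (adjusted p = 0.161) or under quantile normalization (0.13, adjusted p = 0.816). These libraries held 12% of 7SL RNA, and their median change ran from 1.65 in the scarcest quintile of genes to -0.11 in the most abundant.

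MLL fusion target genes fell (3 rose, 24 fell, 2 not passed, median -2.33, adjusted p = 1.43e-10; adjusted p = 0.203 with an estimated correlation). HOXA5 (-6.98), HOXA6 (-6.10), HOXA7 (-5.96), HOXA11 (-5.73), HOXA10 (-4.50), CDK6 (-3.67) and PBX3 (-2.42) fell, and CPEB2 rose by 1.09. MYC fell by 1.62, which was not called under housekeeping scaling (-0.34, adjusted p = 0.0655), and DOT1L rose by 0.61 (adjusted p = 0.00827). MYC targets and ribosome biogenesis fell (0 rose, 24 fell, 2 not passed, median -1.10, adjusted p = 1.95e-11; adjusted p = 0.203 with an estimated correlation), with NME1 at -2.27 and TFRC at -1.83, and 25 fell when adjusted over the list alone. ABC drug transporters rose (13 rose, 1 fell, 1 not passed, median 1.03, adjusted p = 0.00906; adjusted p = 0.439 with an estimated correlation), led by ABCG1 (3.23), ABCC3 (2.77) and ABCG2 (1.77), while ABCB10 fell by 0.42.

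Cholesterol biosynthesis fell (1 rose, 18 fell, 4 not passed, median -0.88, adjusted p = 4.76e-07; adjusted p = 0.332 with an estimated correlation), with DHCR7 at -1.95. Cell cycle and mitosis fell (2 rose, 23 fell, 7 not passed, median -0.62, adjusted p = 1.38e-06; adjusted p = 0.383 with an estimated correlation), with PCNA at -2.10, TYMS at -1.70 and BUB1B at 0.27. MHC class II (1 rose, 11 fell, 2 not passed, median -1.12, adjusted p = 7.24e-05; adjusted p = 0.383 with an estimated correlation) and class I genes (2 rose, 9 fell, 1 not passed, median -0.45, adjusted p = 0.00744; adjusted p = 0.439 with an estimated correlation) fell, with HLA-DRA at -3.08 and B2M at -1.73. Heat shock genes fell (0 rose, 8 fell, 4 not passed, median -0.98, adjusted p = 0.000385; adjusted p = 0.383 with an estimated correlation), with HSPE1 at -1.94. The unfolded protein and amino acid response fell (5 rose, 14 fell, 5 not passed, median -0.67, adjusted p = 0.00160; adjusted p = 0.383 with an estimated correlation), with PSAT1 at -2.33 and the cystine transporter SLC7A11 at 1.19. Adhesion and migration fell (2 rose, 14 fell, 6 not passed, median -0.76, adjusted p = 0.00104; adjusted p = 0.439 with an estimated correlation), with CD9 at -2.45, while ITGB3 rose by 2.00. All 12 housekeeping genes fell (median -1.21, adjusted p = 1.13e-05; adjusted p = 0.383 with an estimated correlation). Resistant library 2 stood apart, with a housekeeping median of 14156 against 7510 and 7342 and CDK6 at 10409 against 5472 and 4828, although the list calls held without it.

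Scaled to the housekeeping genes, the medians of the MHC class II (0.16), MHC class I (0.83), cell cycle (0.66), MYC target (0.18), cholesterol (0.39), amino acid response (0.60), heat shock (0.30), adhesion (0.52) and housekeeping (0.07) lists turned positive, while MLL targets and ABC transporters kept their direction. The MHC class I call ended under quantile normalization (0.331), cyclic loess (0.217) and a mean of at least 300 (0.0891), and the adhesion call under quantile normalization (0.0742). Housekeeping scaling ended the calls of MHC class I (0.539), adhesion (0.292), cell cycle (0.0991) and the amino acid response (0.0607). The largest rises were of DEFA1 (10.98), C9orf131 (9.70), TMEM14E (9.44), FAM196B and NRN1, with the last 2 listed at 0 in the controls and at 1011 and 572 in resistant cells, and of 5 genes without an official symbol. The largest falls included HOXA5, HOXA6 and HOXA7, ALX1 (-6.38), the zinc finger gene ZNF521 (-6.18), EFEMP1 (-6.14), NKAIN2 (-5.94), C10orf114, listed at 0 in resistant cells and at 141 in the controls, and 2 genes without an official symbol. In all, 13668 genes were called, 8541 higher and 5127 lower, with 5514 and 2122 at least 2-fold, and 77.8% showed no overlap (10% by chance). The median of all genes, 0.34, was 0.13 with the median of ratios, -0.03 with quantile normalization, -0.01 with cyclic loess, 0.45 with total scaling and 1.60 with housekeeping scaling. Higher genes, 62.5% of the calls, were 49.4% under cyclic loess, 48.3% under quantile normalization, 48.7% among genes with a mean of at least 300 and 96.6% under housekeeping scaling.

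The NOMO-1 interaction asked the same of the NOMO-1 responses. Cell cycle, amino acid response, cholesterol and heat shock genes had fallen less, each against its own control, in resistant cells than in day 10 cells at the preset correlation. None of these 4 calls held with an estimated correlation (lowest adjusted p = 0.166), and the cholesterol median turned to -0.10 under housekeeping scaling. Relative to the day 10 control, the cell cycle median was -0.36 (long-term control), -1.17 (resistant) and -1.84 (day 10 treated). For the amino acid response these were -0.71, -1.39 and -1.80, for cholesterol -0.17, -1.10 and -1.37, and for heat shock -0.33, -1.47 and -2.09. Part of each difference therefore lay between the controls. A shift between the experiments cannot be told apart from a change in the long-term control. HOXA9 did not pass the test (0.68, adjusted p = 0.202). FLT3 differed by 3.05 (SE 0.336), MEIS1 by 1.98 (SE 0.257), HOXA10 by 1.35, CDK6 by 0.99, BCL2 by 0.92 and PBX3 by 0.56. In the day 10 treated libraries MEIS1 (15.7 to 24.3) and HOXA10 (19.7 to 25.4) were scarce. Olfactory receptor genes averaged 11.1 to 12.7 per kb of transcript there. The size of the MEIS1 and HOXA10 differences may therefore depend on the floor. Under housekeeping scaling BCL2 (0.21, adjusted p = 0.382) and CDK6 (0.28, adjusted p = 0.206) were not called and PBX3 turned (-0.15). Neither DOT1L (-0.58, adjusted p = 0.0698), ABCB1 (0.26, adjusted p = 0.728) nor MYC (-0.14, adjusted p = 0.439) was called. With a pseudocount of 10, however, ABCB1 was called (0.84, adjusted p = 0.00797). DOT1L was called under quantile normalization (-0.66), cyclic loess (-0.73) and housekeeping scaling (-1.29), without resistant library 3 (-0.71, adjusted p = 0.0327) and without day 10 treated library 2 (-0.72, adjusted p = 0.0332), and MYC under housekeeping scaling (-0.86, adjusted p = 0.0124).

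Cell cycle and mitosis (28 higher, 2 lower, 2 not passed, median 1.17, adjusted p = 3.38e-10; adjusted p = 0.385 with an estimated correlation) was higher, with CCNA2 at 2.03 and UBE2C at 1.97. The unfolded protein and amino acid response (19 higher, 0 lower, 5 not passed, median 1.39, adjusted p = 3.38e-10; adjusted p = 0.166 with an estimated correlation) was higher, with PHGDH at 5.94, ASNS at 4.08 and PSAT1 at 3.65, and 20 members passed when adjusted over the list alone. Cholesterol biosynthesis (13 higher, 0 lower, 10 not passed, median 0.61, adjusted p = 0.000383; adjusted p = 0.446 with an estimated correlation) was higher, with DHCR7 at 1.64. Heat shock (9 higher, 0 lower, 3 not passed, median 1.18, adjusted p = 0.00164; adjusted p = 0.446 with an estimated correlation) was higher, DNAJA1 by 2.54, and 10 members passed when adjusted over the list alone. In all, 9498 genes differed, 4328 higher and 5170 lower, and higher genes went from 45.6% of the calls to 15.9% under housekeeping scaling, 51.5% under the median of ratios and 50.8% under cyclic loess. GZMA (8.80), FAM25B (8.17) and LYPD6B (8.13) were among the most positive, LTF (-7.87), LIN7A (-7.51), HRC (-7.14), KNDC1 (-7.09) and RORB (-6.66) the most negative. The CDK6 and PBX3 calls were each lost without any 1 of the long-term control or day 10 control libraries or without day 10 treated library 1 (adjusted p from 0.0551 to 0.0864 for CDK6 and 0.0637 to 0.0991 for PBX3), PBX3 also without resistant library 2 (0.0907) or 3 (0.0645), and HOXA9 was called without day 10 treated library 3 (adjusted p = 0.035).

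Of the genes raised at day 10 in NOMO-1, 7326 were also higher in resistant cells (4304 if independent) and 203 were lower. Of those lowered, 4462 were also lower (1693 if independent) and 332 were higher. The median resistant change was 1.06 over the raised and -0.69 over the lowered genes, 1.81 and -0.20 under housekeeping scaling, and 0.70 for raised genes with a mean of at least 300. Both responses share the trend with abundance, so the overlap is not evidence of retention alone. For changes of at least 2-fold, 4694 were shared upward and 1879 downward, against 2185 and 460 if independent.

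The last comparison asked whether the lines responded alike. The fusion targets HOXA9, HOXA10, MEIS1 and CDK6 fell further in NOMO-1 at both times under every scaling. Against the long-term controls ABCB1 rose further in resistant KOPN-8. That control held less ABCB1 than the day 10 control in KOPN-8 (5.72 against 35.5). In NOMO-1 it held more (16.1 to 23.4 against 0 to 1.70). The ABCB1 difference therefore rests on the control used, and it was not tested against the day 10 controls. The NOMO-1 response minus the KOPN-8 response at day 10 was -4.31 for MEIS1, -4.02 for HOXA9, -3.78 for FLT3, -3.46 for HOXA10, -3.16 for CDK6, -2.09 for PBX3, -0.98 for MYC, -0.49 for BCL2 and 1.78 for DOT1L. At day 10 BCL2 turned under housekeeping scaling (1.16) and cyclic loess (0.15), and MYC under housekeeping scaling (0.67). ABCB1 was not called (0.46, adjusted p = 0.344), but was under quantile normalization (-0.91), cyclic loess (-1.70) and housekeeping scaling (1.57). Between the resistant responses it was -5.14 for ABCB1, -4.38 for HOXA9, -3.95 for HOXA10, -3.82 for MEIS1, -3.43 for CDK6, -1.62 for BCL2, -1.23 for PBX3, -1.22 for MYC, -1.10 for FLT3 and 0.58 for DOT1L. Under housekeeping scaling FLT3 (-0.05, adjusted p = 0.826), MYC (-0.17, adjusted p = 0.360) and PBX3 (-0.18) were not called.

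Between the day 10 responses 15135 of 19018 genes differed, 9009 higher in NOMO-1 and 6126 lower, and between the resistant responses 13792, 8494 higher and 5298 lower. The balance turned at day 10 under cyclic loess (6421 higher, 7960 lower), quantile normalization (7154, 7363) and a mean of at least 300 (3974, 4928), as it did for the resistant responses (5702 and 6912, 6356 and 6703, 3715 and 4430). Under housekeeping scaling 90.1% and 90.4% were higher. Of 14737 genes tested in both lines, 1987 rose in both at day 10 (2049 if independent), 2023 fell in both (1526), and 1700 and 1400 went opposite ways. In resistant cells 1264 rose in both (1805) and 1473 fell in both (1677), while 1984 and 2274 went opposite ways. For changes of at least 2-fold, 300 rose and 224 fell in both lines at day 10 (180 and 181 if independent), and 271 and 92 in resistant cells (168 and 99.4).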

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

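Of the tests below, those of scaling, of background over all genes, of transcript length, of the ABCB1 neighbours and of ABCB4 were chosen after the result was seen, while the first background test, the batch test and the splits of the libraries were fixed before. The genes, lists and counts of the next 3 paragraphs were picked out because the responses of 2 groups differed by a test of the difference itself. The 3 patterns after them were chosen from the values.

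Within KOPN-8, 8841 genes responded differently in resistant and day 10 cells. The lists that differed were cell cycle and mitosis (adjusted p = 2.10e-19), cholesterol biosynthesis (5.92e-13), MLL fusion targets (7.03e-10), heat shock (0.00287) and MHC class II (0.00960). The calls of heat shock and MHC class II were lost with an estimated correlation (adjusted p = 0.329 for each). For the cell cycle list the median relative to the day 10 control was -0.88 in the long-term control, against -0.14 in resistant and -0.19 in day 10 treated cells. A shift between the experiments cannot be told apart from a change in the long-term control there. Genes with a more positive response in resistant cells were TLL1 (7.37), CARKD (6.99), DDIT4L (6.68), WDR11 (6.64), ABCB1 (5.86), BCL2 (2.05), HOXA10 (1.84), MEIS1 (1.49), CDK6 (1.26), HOXA9 (1.04), DOT1L (0.62) and FLT3 (0.36). More negative were SLC6A8 (-8.33), OSR2 (-6.45), DNAJC15 (-6.30), TRO (-6.16), FAM127B (-6.08) and PBX3 (-0.30). BCL2 in resistant cells (3414) was near the long-term control (3575) and below the day 10 control (7022). The values of TLL1 and DDIT4L depend on the pseudocount, because a control group is listed at 0. At CARKD, DDIT4L, WDR11, SLC6A8, OSR2 and DNAJC15 the long-term control stood at least 4-fold from each of the other groups. Resistant cells did so at TLL1, TRO, FAM127B and DNAJC15. Relative to the day 10 control, DDIT4L was at -6.93 in the long-term control and -0.87 in resistant cells, and CARKD at -5.39 and 1.09.

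Within NOMO-1, 9498 genes responded differently. The lists were cell cycle and mitosis (adjusted p = 3.38e-10), the unfolded protein and amino acid response (3.38e-10), cholesterol biosynthesis (0.000383) and heat shock (0.00164). All 4 calls were lost with an estimated correlation (adjusted p = 0.385, 0.166, 0.446 and 0.446), and the cholesterol median turned to -0.10 under housekeeping scaling. In all 4 lists the long-term control lay below the day 10 control, so part of each difference lay between the controls. The day 10 control alone was at least 4-fold from each other group at 306 of 14971 genes. That count was 57 for the long-term control, 162 for resistant and 338 for day 10 treated cells. Genes with a more positive response in resistant cells were FOXN4 (8.94), GZMA (8.80), FAM25B (8.17), LYPD6B (8.13), HS6ST3 (7.62), FLT3 (3.05), MEIS1 (1.98), HOXA10 (1.35), CDK6 (0.99), BCL2 (0.92) and PBX3 (0.56). The CDK6 and PBX3 calls were lost without the trend, under total scaling and without any 1 of at least 7 libraries, PBX3 turned under housekeeping scaling (-0.15), and BCL2 was not called there (0.21, adjusted p = 0.382). More negative were LTF (-7.87), LIN7A (-7.51), HRC (-7.14), KNDC1 (-7.09) and RORB (-6.66). FOXN4 and HS6ST3 are listed at 0 in both day 10 groups, so their values depend on the pseudocount. FAM25B was near 0 in both long-term groups, at 3.07 and 4.94, so its value comes mainly from the day 10 cells. MEIS1 and HOXA10 were scarce in the day 10 treated libraries, so the size of their differences may depend on the floor.

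Between the lines, NOMO-1 minus KOPN-8, 15135 genes differed at day 10: DOT1L (1.78), BCL2 (-0.49), MYC (-0.98), PBX3 (-2.09), CDK6 (-3.16), HOXA10 (-3.46), FLT3 (-3.78), HOXA9 (-4.02) and MEIS1 (-4.31) among them. Of these, BCL2 and MYC turned under housekeeping scaling (1.16 and 0.67) and BCL2 under cyclic loess (0.15). In resistant cells 13792 differed, with DOT1L (0.58), FLT3 (-1.10), MYC (-1.22), PBX3 (-1.23), BCL2 (-1.62), CDK6 (-3.43), MEIS1 (-3.82), HOXA10 (-3.95), HOXA9 (-4.38) and ABCB1 (-5.14), of which FLT3, MYC and PBX3 were not called under housekeeping scaling (-0.05, -0.17 and -0.18). ABCB1 in the long-term control was below the day 10 control in KOPN-8 and above it in NOMO-1. Its difference between the lines therefore rests on the control used.

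The first pattern weighed is that scarce transcripts were higher and abundant ones lower in treated NOMO-1 libraries. Scaling of whole libraries would not by itself make this pattern, because 1 factor per library moves scarce and abundant genes alike. The test of scaling, a difference of 2.11 between the scarcest and the most abundant quintile at day 10, restates the pattern and so decides nothing further. Transcript length was argued against, since the correlation of abundance with change was -0.319 in the length quintile where it was weakest. Background over all transcripts stays open: of 3 forms of that test 2 were void, because only 72.0% of the scarcest quintile and 72.4% of the next had a known length. In the last form, over all genes, the correlation went from -0.337 to -0.126 after the mean background was subtracted and to -0.033 after its 95th percentile was. The background was taken from scarce olfactory receptor genes, which were themselves higher in treated libraries. Subtracting it lowers scarce genes most there, and the 95th percentile left 12.2% of genes at 0 in all libraries. The trend would weaken in this way whatever its cause, so the values do not show how much of it is background. A biological change in RNA content may also contribute and cannot be told apart from a technical one here, because treatment and library composition moved together.

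The second pattern is that the KOPN-8 long-term control stood apart from the other KOPN-8 groups. It alone was at least 4-fold from the 3 others at 85 of 11679 genes, against 55 for resistant, 63 for day 10 treated and 10 for day 10 control cells. A batch between the experiments was tested at 180 genes at least 4-fold apart between the vehicle controls. Resistant cells were at least 2-fold from the day 10 control in the same direction at 38.9% of them (95% interval 31.7% to 46.4%). This share lay below that set beforehand for a batch. The drug response of resistant cells could offset a batch shift at these genes, so the test does not decide and a batch stays open. Smaller moves in the same direction were not counted, and genes less than 4-fold apart were not tested. The long-term control libraries also differed in composition, with 6.84% of 7SL RNA against 4.01% to 4.30% and a housekeeping median of 31998 against 19835 to 23072, and whether that goes with the pattern was not tested. Gene by gene, 8 of the 12 housekeeping genes were called lower there than in the day 10 control, and 3 higher. A change in the cells kept in vehicle stays open and was not tested, since the count of 85 is the pattern itself and each group comes from 1 named pellet.

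The third pattern is the level of ABCB1 in resistant KOPN-8 cells. Gain of the chromosome segment was argued against, since the 20 nearest tested genes had a median change of 0.110 (95% bootstrap interval -0.27 to 0.43), although ADAM22 (2.32), CLDN12 (2.17) and CDK14 (1.84) among them were higher. Reads shared with its paralog ABCB4 were argued against as well, because ABCB4 changed by 0.0717. A gain of ABCB1 without most of these neighbours and a change in its transcription both stay open, and neither was tested.

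The libraries of each treated comparison were also split in all 10 ways of 3 against 3, the real split among them, and 100 splits were drawn for each difference of responses. With 10 splits a share below 0.05 cannot arise, so the counts only describe. Of 10 splits, 1 had a gene count as large as the real one in KOPN-8 at day 10 (8644; highest other 1), in resistant KOPN-8 (9884; highest other 0), in NOMO-1 at day 10 (15558; highest other 0) and in resistant NOMO-1 (13668; highest other 0). For lists called, the splits with a count as large were 1 (12; highest other 9), 1 (7; highest other 4), 2 (9; highest other 9) and 5 (11; highest other 12) in the same order. Of 100 splits, 1 had as many genes as the KOPN-8 interaction (8841, highest other 6275) and 2 as many as the NOMO-1 interaction (9498, highest other 9808). For each difference between the lines 1 split had as many (15135 and 13792, highest others 4829 and 2916). These shares do not exclude chance, because splits that mix treated and control libraries widen the spread within groups, which by itself lowers their gene counts. Chance between cultures was not tested, since the libraries of a group share 1 pellet name. For the number of lists, 46 of 100 reached the 5 of the KOPN-8 interaction (highest other 12) and 86 of 100 the 4 of the NOMO-1 interaction (highest other 17), so chance is not excluded for the number of lists, and splits that mix treated and control libraries call more.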

How the results depend on the processing

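No paired analysis was possible because the columns of the table carry no replicate number, so the intended replicate block was not run; DESeq2 and edgeR were not run because the values are not counts. Most results kept their side of the threshold, but 42 list calls were lost with an estimated correlation. Direction was compared only for medians and for results called as reported. For lists it is that of the list test, so list medians that turned under housekeeping scaling are not counted as reversed. For counts and medians, the alternatives fixed beforehand gave 328 that stayed the same and 52 that moved, the added ones 118 same, 33 moved and 1 reversed, and leaving out a library 524 same and 4 moved. For list tests these numbers were 1638 same, 91 stronger and 57 weaker (fixed beforehand), 614 same, 16 stronger and 27 weaker (added), and 1994 same, 12 stronger and 10 weaker (left out). For named genes they were 1543 same, 5 stronger, 7 weaker and 1 reversed (fixed beforehand), 623 same, 9 stronger, 9 weaker and 7 reversed (added), and 2348 same, 4 stronger and 18 weaker (left out). Apart from the 10 genes always reported, named genes were picked for large called changes in the same data. That they stayed the same therefore says little. Where a value below changed, the cause was not tested unless it is named.

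With an estimated correlation, camera called 3, 0 and 3 lists in the KOPN-8 day 10, resistant and interaction tests and 0, 0 and 0 in those of NOMO-1. Fry, which tests each list against no change, called 21, 24, 22, 26, 20 and 20 in that order. With only the 6 libraries compared, 4 lists were called in resistant KOPN-8.

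With calls of at least 2-fold, 571 genes of KOPN-8 were retained (medians 0.84 and -0.65) and 6573 of NOMO-1 (1.36 and -0.95), and the lines shared 524 genes at day 10 and 363 in resistant cells; fewer genes pass by construction. Tested against a minimum of 1.5-fold, 1522 genes (598 higher, 924 lower) were called in KOPN-8 at day 10, 2034 (1095, 939) in resistant cells and 2055 (1252, 803) in the interaction. In NOMO-1 the stricter test called 6969 (4848, 2121) in resistant cells and 3438 (1556, 1882) in the interaction, and 8328 (5462, 2866) between the resistant responses. It left 543 retained genes in KOPN-8 (medians 0.66 and -0.53), 5985 in NOMO-1 (1.30 and -0.91), and 591 and 335 shared by the lines.

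The median resistant change of genes raised at day 10 in NOMO-1 was 0.93 with a pseudocount of 10, 0.96 with a filter at 50, 0.74 with quantile normalization, 0.74 with cyclic loess and 0.70 with a mean of at least 300. For lowered genes it was -0.89, -0.80 and -0.80 with quantile normalization, cyclic loess and the median of ratios. Among genes with a mean of at least 300, where fewer genes are tested, 3388 were lower in resistant KOPN-8. NOMO-1 then had 9300 calls at day 10 (4534 higher), 8173 in resistant cells (3978 higher) and 6245 in the interaction (3136 lower), with 7234 retained. The resistant cells of both lines shared 1807, and the lines differed at 8902 (3974 higher) and 8145 (3715 higher).

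As deposited, all 12 housekeeping genes fell in both NOMO-1 comparisons. Upper-quartile scaling rests on an assumption of its own, and the values do not decide between it and housekeeping scaling. Housekeeping scaling assumes that these 12 genes are constant. It gave 2736 higher and 8243 lower genes and 4 lists in resistant KOPN-8, 2755 higher in its interaction, 15927 and 1142 in NOMO-1 at day 10, 15858 and 557 with 6 lists in resistant NOMO-1, and 1407 higher in its interaction. The retained medians became -0.13, which is reversed, and -0.36 in KOPN-8, and 1.81 and -0.20 in NOMO-1. Between the lines 15003 and 1642 genes differed at day 10 and 13944 and 1485 in resistant cells. Higher genes became 90.1% and 90.4% of these, against 59.5% and 61.6%, 49.3% and 48.7% under quantile normalization and 44.6% and 45.2% under cyclic loess; in the KOPN-8 interaction they went from 47.9% to 28.7%. MYC in NOMO-1 at day 10 was reversed to 0.51 and PBX3 in the NOMO-1 interaction to -0.15, and between the lines at day 10 BCL2 to 1.16 and MYC to 0.67. Cyclic loess reversed that BCL2 difference to 0.15. ABCB1 was reversed in NOMO-1 at day 10 under quantile normalization (-0.78) and cyclic loess (-0.98), and in resistant NOMO-1 under cyclic loess (-0.64); the cause was not tested.

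Leaving out a library gave 4 to 10 lists in resistant KOPN-8, 4 to 8 in the NOMO-1 interaction, and 0.96 to 1.18 for the retained median of raised NOMO-1 genes. Replicate spread limits NOMO-1 more, where the median SE was 0.196 against 0.0670 in KOPN-8. With the spread of the real genes a simulated 1.5-fold change was recovered in 26.9% of genes at day 10, against 74.6%. In resistant cells these shares were 22.4% and 68.7%, and in the interactions 7.46% and 56.7%. Few genes were changed in the simulation, so its adjusted threshold was stricter than that of the real fits. These shares compare the lines and are not the power of the real comparisons.

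Some lists not called here were called under alternatives. In resistant KOPN-8 these were MHC class I under quantile normalization (adjusted p = 0.0105), cyclic loess (0.00468), housekeeping scaling (0.0274) and without resistant library 3 (0.0425), the interferon response without that library (0.0464), and NF-kB and xenobiotic metabolism with a filter at 50 (0.0213 and 0.0447) or a mean of at least 300 (0.0195 and 0.0319). In the KOPN-8 interaction they were MYC targets and ribosome biogenesis without a filter (0.0408) and under quantile normalization (0.010), total scaling (0.0368), housekeeping scaling (0.00645) and cyclic loess (0.00091), and B cell lineage genes under cyclic loess (0.0461). In NOMO-1 at day 10, RAS-MAPK output was called with a mean of at least 300 (0.0461) and under housekeeping scaling (0.0418). In the NOMO-1 interaction MLL fusion targets were called with a mean of at least 300 (0.0459) and without resistant library 1 (0.0342), and xenobiotic metabolism without a filter (0.0394), under cyclic loess (0.0417), with a mean of at least 300 (0.00945) and without resistant library 1 (0.0341) or 3 (0.0393). Myeloid genes were called there under cyclic loess (0.0417), housekeeping scaling (0.0492) and without resistant library 2 (0.0247), WNT targets under housekeeping scaling (0.0492), MYC targets without resistant library 1 (0.0341) and housekeeping genes without library 1 (0.0341) or 3 (0.0311).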

Other observations

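The gene sets described here were fixed beforehand, and their examples were chosen after the results were seen. In KOPN-8 at day 10 several families did not move as lists although single members did. Myeloid and monocyte genes (5 rose, 5 fell, 9 not passed, adjusted p = 0.651) held CD86, a costimulatory receptor, at 5.33. Apoptosis regulators (9 rose, 4 fell, 9 not passed, adjusted p = 0.534) held the pro-apoptotic genes BMF at 3.50 and HRK at 3.40 beside BCL2 at -2.12. Xenobiotic metabolism (5 rose, 6 fell, 3 not passed, adjusted p = 0.689) held ALDH1A1 at 4.75, and its median of -0.06 and mean of 0.31 differ in sign. DOT1L and MLL complex members (11 rose, 4 fell, 5 not passed, adjusted p = 0.534) had a median of 0.17 and a mean of -0.02. The interferon response (6 rose, 12 fell, 7 not passed, adjusted p = 0.297), CDK inhibitors and p53 targets (8 rose, 13 fell, 2 not passed, adjusted p = 0.281), other histone methylation enzymes (11 rose, 5 fell, 9 not passed, adjusted p = 0.567), T and NK cell genes (4 rose, 1 fell, 4 not passed, adjusted p = 0.898), erythroid and megakaryocyte genes (1 rose, 1 fell, 6 not passed, adjusted p = 0.898) and stromal and epithelial genes (1 rose, 2 fell, 4 not passed, adjusted p = 0.815) were not called either. These 10 lists were called in none of the comparisons as reported. In resistant KOPN-8, CYBB was at 6.29, the apoptosis inhibitor BIRC3 at 4.18, the histone demethylase KDM5B at -2.10 and the methyltransferase EZH2 at 0.92.

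In NOMO-1 at day 10, members of the myeloid list moved both ways and the list was not called (16 rose, 11 fell, 9 not passed, adjusted p = 0.965). The macrophage receptor CSF1R was at 3.58, ITGAX at 3.46 and CD36 at 3.11, while the granule enzymes CTSG, PRTN3 and MPO were at -4.98, -2.79 and -2.17. In resistant NOMO-1, MPO was at 1.52, CD14 at 1.96 and CD36 at 2.33. Erythroid and megakaryocyte genes (10 rose, 2 fell, 2 not passed, median 2.65, adjusted p = 0.226) and T and NK cell genes (9 rose, 2 fell, 6 not passed, median 2.19, adjusted p = 0.496) had high medians in the libraries where olfactory receptor genes were also higher. RAS-MAPK output (14 rose, 4 fell, 4 not passed, adjusted p = 0.182) held JUN at 3.26 and the inhibitor SPRED1 at 2.67. In resistant NOMO-1 the feedback genes DUSP4 and SPRY2 were at 3.30 and 2.10.

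Lists that were not called had adjusted p from 0.178 to 0.902 in KOPN-8 at day 10 (16 lists), 0.0698 to 0.992 in resistant KOPN-8 (21), 0.0862 to 0.995 in its interaction (23), 0.162 to 0.965 in NOMO-1 at day 10 (19), 0.347 to 0.963 in resistant NOMO-1 (17) and 0.0764 to 0.986 in its interaction (24).

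Of 320 genes at least 4-fold apart in resistant KOPN-8, 240 were also at least 2-fold from the day 10 control in the same direction; both comparisons share the resistant libraries. NOMO-1 day 10 treated library 1 and resistant library 2 stood apart from the other libraries of their groups. The oligo-dT selection named in the labels and the 7SL share of 21.5% to 40.8% in NOMO-1 day 10 treated libraries stand side by side here, with no explanation tested. Of 24 pairs of libraries of the same group, 0 were identical.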
